A study of Homo sapiens with 6 samples.

How the data were processed

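RNA was extracted from TTC642 rhabdoid tumour cells grown in RPMI with serum, 3 libraries after 24 h in 1 µM idasanutlin and 3 after 24 h in 0.01% DMSO. Per the labels' protocols, total RNA was taken up in TRIzol, cleaned on RNeasy MinElute columns and made into libraries with the NEBNext Ultra RNA kit, which does not mark strand. The submitters' processing notes name STAR, RSEM, DESeq2 and the genome build hg19, without versions or the role of each. The deposited files give 1 table per library with the columns of RSEM's gene-level output. Per the file headers, the authors deposited the expected count of each gene, in which RSEM divides reads shared between genes by its model, and no normalisation is applied to it. The TPM column was also deposited by the authors, per the file headers, as RSEM's abundance per effective transcript length, and it sums to the same total in every library. Other deposited columns used here, per the file headers, are RSEM's posterior SD of each count, which is 0 where a gene shares no reads, and the mean transcript length and effective length. Genes carry versioned Ensembl IDs joined to a symbol, so names come from the files. The annotation release and any filter on the genes are not stated in the labels. No coordinates are given, since no annotation of hg19 was used here.

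From the expected counts, rounded to whole numbers, the idasanutlin libraries were compared with the DMSO libraries in edgeR 4.0.16 under R 4.3.3, with TMM factors, genes kept by filterByExpr at its default settings and the quasi-likelihood test of glmQLFit and glmQLFTest, two-sided. P-values were adjusted by the Benjamini-Hochberg method over the 16587 tested genes, and an adjusted p below 0.05 counts as a pass. The standard error of a log2 fold change is its size divided by the square root of the F statistic. Group means and SDs are of the deposited TPM values, and CPM values use TMM-scaled library totals. The biological coefficient of variation was 0.176. No sample was left out of the comparison.

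The labels number the replicates without saying that same-numbered libraries belong together. To test this, each library's deviation from its group mean was correlated between the groups over 10073 genes with a log2 CPM above 3. All same-numbered correlations lay above 0.1, and each library correlated best with its own number (0.47 to 0.59, against -0.51 to 0.06 for other numbers), so the numbers were taken to pair the libraries and a fit with the replicate number as a block was run. Deviations from a group mean cancel over the group, so high same-numbered values push the others down. With 3 libraries per group few matchings exist, so the pairing could also be luck. Its value is printed where it changes the call of a named gene or of a list, or moves a count of calls by over 1.5 times. Libraries of a group differed by more than repeated sequencing of 1 library would give, with a chi-square per degree of freedom of 15 to 59.5 between pairs of libraries over genes of at least 50 counts.

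The 30 gene lists were fixed before the data were examined, from textbook knowledge: 5 lists of genes activated by p53 (arrest and feedback, apoptosis, DNA repair, metabolism and transport, others), G1/S and DNA replication, G2/M and mitosis, homologous recombination and Fanconi anaemia repair, histones, the BCL2 family, regulators of p53, SWI/SNF subunits, ribosome biogenesis, ribosomal proteins, cholesterol, interferon, MHC class I, stress responses, secreted factors of senescent cells, extracellular matrix, contractile, neuronal, lysosome and autophagy, glycolysis, NRF2, immediate early and mitochondrially encoded genes, and markers of haematopoietic, epithelial and endothelial cells. Each was tested with camera in limma 3.58.1 with a preset correlation of 0.01, two-sided, adjusted over the 30 lists. Camera with a correlation estimated per list was run beside it, as was fry, which tests whether the members of a list move on balance one way and compares them with no other genes. Counts of members are at the edgeR adjusted p over all tested genes, and a second count adjusts over the list alone. Lists of DUX4 targets and epidermal genes were added after the gene table was seen.

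Genes were named by a rule set before the data were examined. It takes MDM2, MDM4, CDKN1A and SMARCB1 whatever their values. It takes the 8 largest rises and 8 largest falls among genes that passed, whose TPM ranges did not overlap between the groups, with a mean TPM of at least 1 in 1 or both groups and a symbol that is not a clone or locus number. It takes the 3 members with the smallest adjusted p in the direction of each list that passed camera, and the 2 with the smallest adjusted p below 0.05 of each other list. Other genes named in the text were picked after their values were seen, as stated beside them. Some genes taken by the rule or picked later are not reported here. Where a group has 0 counts of a gene, the fold is a lower bound against a floor of 3 counts over the group. With 1 to 3 counts, the ratio is given with an exact 95% interval from the binomial test. Such floors and intervals cover counting error only, since reads are not independent molecules.

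The fit was tested on simulated data with 200 genes changed and 15704 genes in the tested step. Gene means were those of the DMSO libraries, with low means raised to a floor. Library sizes and dispersions were those of these 6 samples. It recovered 16%, 54%, 82% and 82% of the 50 genes changed 1.5, 2, 4 and 8-fold, and called 4 of 15492 unchanged genes, 2.7% of its 148 calls. A list raised 2-fold was called, and 0 others were. The run was set to stop if 8-fold recovery or the false share missed a preset limit, or if the raised list was not called. These outcomes could therefore not have been reported otherwise. Genes were drawn independently, whereas the estimated correlation within the real lists reached 0.82, for mitosis. The simulation therefore does not test false calls of lists at the preset correlation. It changed far fewer genes than the 6960 called in the data, so its share of false calls need not carry over. Exon overlaps of 173 named genes with their neighbours were read from the GENCODE 29 annotation, in which 170 had a match. Its build differs from that of the files, so only the share of overlapping exons was taken from it.

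Alternatives set before the data were examined were RLE and upper-quartile factors, DESeq2 1.42.0, limma-voom on unrounded counts, no filter, a stricter filter (mean CPM of at least 1), the replicate block, limma on log2(TPM + 1) and log2(TPM + 0.1), and leaving out each library in turn. The lists were rerun with RLE factors, the stricter filter, the block, log2(TPM + 1) and each library left out. Leaving out both number 2 libraries was added after the principal components were seen. Every other split of the 6 libraries into 3 and 3 was fitted in the same way, without the block.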

Results

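RNA from TTC642, an established cell line derived from a malignant rhabdoid tumour of soft tissue, was sequenced in 6 libraries. The 3 libraries of the treated group came from cells exposed to 1 µM idasanutlin for 24 h, and the 3 control libraries came from cells given 0.01% DMSO. Idasanutlin occupies the pocket through which MDM2, a ubiquitin ligase, binds the tumour suppressor p53. The title of the series names MDM2 and its relative MDM4 as vulnerabilities of this tumour type, and the design asks how the transcriptome of these cells differs between drug and solvent. The total expected count was 32275633, 27424466 and 31404615 in DMSO replicates 1 to 3 and 32123682, 34056156 and 20150329 in idasanutlin replicates 1 to 3. Of the genes in the files, 29618 had an expected count above 0 in 1 or more libraries and 16587 were tested. The labels do not say whether replicates were separate cultures, so the p-values measure only the spread between these samples, which may be technical in part.

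MDM2 and CDKN1A, a pair of genes that p53 activates, both rose, and MDM4 rose slightly. MDM2 (ENSG00000135679.17) rose 19.1-fold, from 39.0 ± 4.56 to 770 ± 71.6 TPM (length-normalised transcript abundance; mean ± SD, n = 3 per group here and below; log2 fold change 4.25, SE 0.124, edgeR adjusted p = 3.1e-07). CDKN1A (ENSG00000124762.9), which encodes the cyclin-dependent kinase inhibitor p21, rose 8.36-fold, from 254 ± 51.4 to 1891 ± 279 TPM (log2 fold change 3.06, SE 0.201, edgeR adjusted p = 9.66e-06). MDM4 (ENSG00000198625.8), the relative of MDM2 that restrains p53 activity, was 1.28-fold higher, at 18.04 ± 2.43 and 21.99 ± 1.86 TPM (log2 fold change 0.36, SE 0.0904, edgeR adjusted p = 0.0126).

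SMARCB1 (ENSG00000099956.13), the SWI/SNF subunit whose loss is typical of rhabdoid tumours, had 40.8 ± 0.76 TPM in DMSO and 31.4 ± 0.912 TPM under idasanutlin. Its log2 fold change of -0.23 (SE 0.0925) did not pass the test (edgeR adjusted p = 0.0768), although the TPM values of the groups did not overlap. With the replicate number as a block, the edgeR adjusted p of SMARCB1 was 0.04, and over all alternatives it ranged from 0.0111 to 0.243. The call of MDM4 was lost on the TPM scale, with a log2 fold change of 0.28 and a limma adjusted p of 0.136 on log2(TPM + 1), and its adjusted p ranged from 0.00425 to 0.136 over the alternatives.

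**Figure D1:**
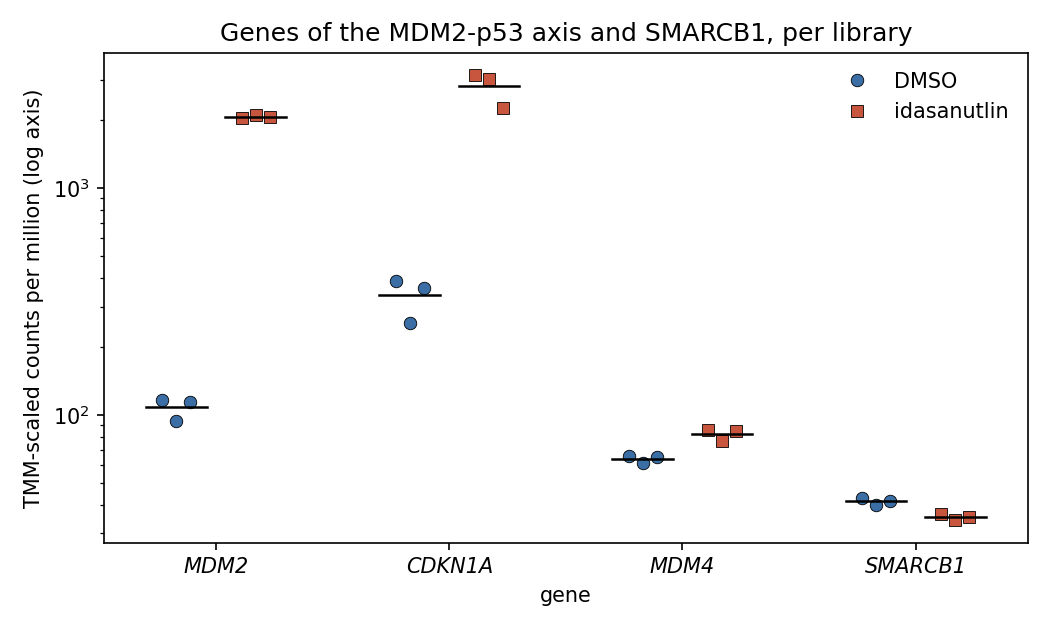
TMM-scaled CPM (vertical log axis) of MDM2, CDKN1A, MDM4 and SMARCB1 in each of the 3 DMSO and 3 idasanutlin libraries, with a point per library and a bar at the group mean. MDM2 lies between 94.1 and 116 in DMSO and between 2027 and 2097 under idasanutlin, while SMARCB1, which did not pass the test, lies between 34.2 and 43.0 over all libraries.

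Across the transcriptome, 6960 of the 16587 tested genes (42%) differed at an edgeR adjusted p below 0.05, of which 3594 were higher and 3366 lower under idasanutlin. Past a doubling, 1922 genes were higher and 1175 were lower. The TPM values of the groups did not overlap for 9082 tested genes (54.8%), where chance gives 10% for exchangeable libraries. That figure ignores any pairing by replicate number. The first principal component held 80.2% of the variance and separated the groups. The second held 9% and set the number 2 libraries of both groups apart, at -44.5 for DMSO and -26.7 for idasanutlin against 12.1 to 25.9 for the others.

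Same-numbered libraries deviated from their group means together, with correlations across 10073 genes of 0.47, 0.59 and 0.50 for numbers 1, 2 and 3, so the replicate number was also fitted as a block. The blocked edgeR fit called 8837 genes, 4413 higher and 4424 lower, and kept 6947 of the 6960. On the TPM scale the median log2 fold change of all tested genes moved from -0.025 to -0.147 with a pseudocount of 1 and to -0.188 with 0.1. There 37% and 37.2% of the calls were higher, against 51.6% by counts, so the balance of rises and falls differs between these settings. Past a doubling, 1060 genes were higher and 1005 lower with the pseudocount of 1, and 1567 and 1511 with 0.1.

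By the fitted log2 fold change, which is not a measured fold for a gene at 0 counts, the 8 largest rises of genes that met the naming rule were in genes with 0 or 1 counts in DMSO. CLCA2, an epithelial gene of the chloride channel accessory family that p53 can activate, had 0 counts in the 3 DMSO libraries and 2046 under idasanutlin, which is at least 782-fold higher against a floor of 3 counts over the group. Against the same floor, DUX4L11, a copy of the embryonic transcription factor gene DUX4, was at least 370-fold higher. WDFY4 was at least 309-fold, the intestinal mucin gene MUC2 at least 272-fold, HHATL-AS1 at least 195-fold, the epithelial galectin gene LGALS7B at least 150-fold and USP29 at least 135-fold higher. The receptor tyrosine kinase gene ALK had 1 count in DMSO and 1384 under idasanutlin, a ratio of 1590 with a counting interval from 284 to 62700. These 8 genes had edgeR adjusted p-values from 1.99e-06 to 9.51e-05.

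Among the 8 genes with the largest falls by the same rule and fit, MKI67, which encodes the proliferation marker Ki-67, went from 26.8 ± 10.5 to 0.187 ± 0.204 TPM (log2 fold change -8.36, SE 0.452). The log2 fold change was -7.91 for the kinetochore gene SKA1, -7.54 for the mitotic spindle gene GTSE1, -7.53 for the replication initiation gene MCM10, -7.48 for SHCBP1 and -7.29 for the spindle checkpoint gene BUB1B. The kinetochore gene SPC25 had 3 counts left under idasanutlin, with DMSO 207 times as high (counting interval 70.6 to 1010). The DNA glycosylase gene NEIL3 had 2 counts left, with DMSO 201 times as high (55.4 to 1670). The edgeR adjusted p-values of these 8 genes ran from 2.74e-06 to 4.17e-05.

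**Figure D2:**
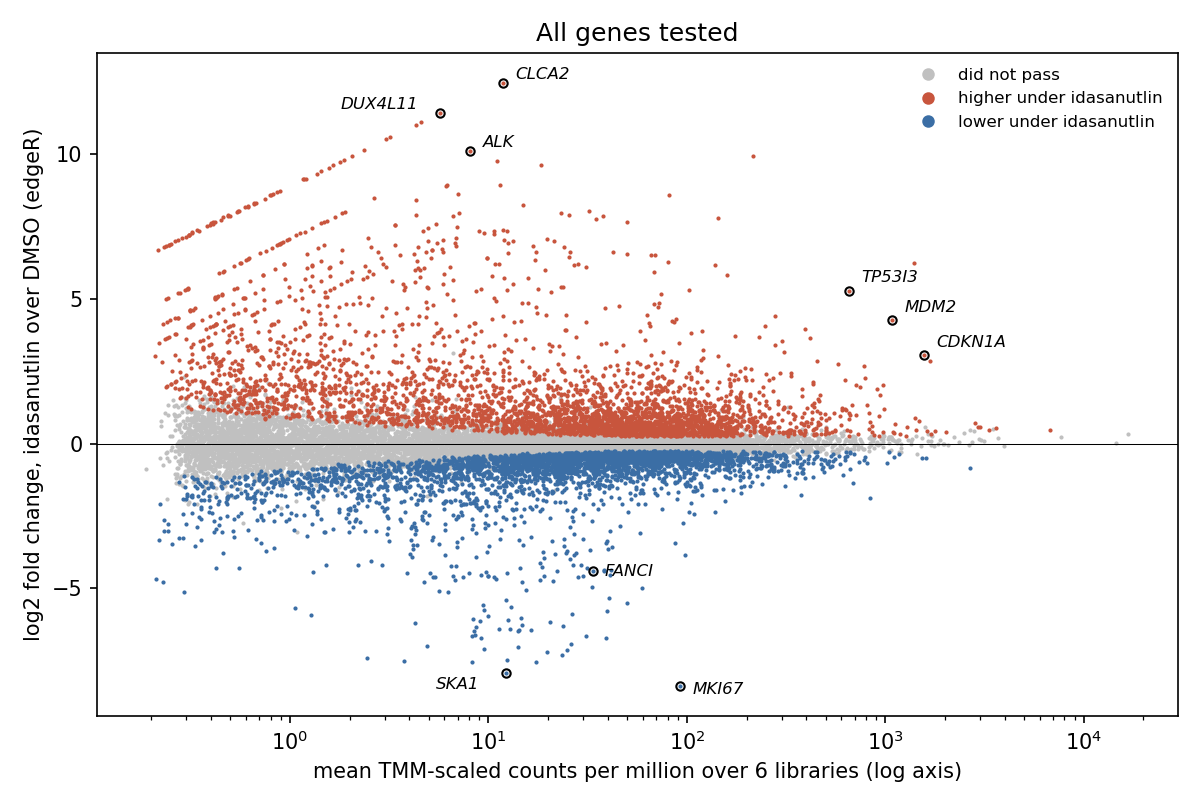
log2 fold change of idasanutlin over DMSO from edgeR (vertical axis) against the mean TMM-scaled CPM over the 6 libraries (horizontal log axis), with a point per tested gene. Red points are the 3594 genes called higher, blue points the 3366 called lower and grey points did not pass. Circles mark named genes, from MKI67 at -8.36 to MDM2 at 4.25 and the fitted values of genes with no DMSO counts at the top, which are not bounds.

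The known target genes of p53 rose in all 5 lists fixed in advance for them, with 0 members falling. Of 21 tested genes of cell-cycle arrest and feedback on p53, 18 rose and 3 did not pass, with a median log2 fold change of 1.79 (camera adjusted p = 2.15e-27). BTG2, an antiproliferative gene, rose from 15.97 to 180 TPM (log2 fold change 3.70), and SESN1, which encodes a sestrin that dampens mTORC1 signalling, from 9.94 to 58.0 TPM (2.67). Of 21 genes of apoptosis and death receptors, 20 rose and 1 did not pass, with a median of 1.92 (camera adjusted p = 1.13e-30). TP53I3, a quinone oxidoreductase gene, rose from 44.5 to 1335 TPM (5.29), PIDD, the scaffold of the PIDDosome that activates caspase-2, from 16.1 to 290 TPM (4.41), and the adaptor gene TRAF4 from 51.9 to 248 TPM (2.38). The exception was the decoy receptor gene TNFRSF10C, singled out after its value was seen, at a log2 fold change of -0.12.

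All 6 p53-activated genes of DNA repair and nucleotide supply rose (median 1.66, camera adjusted p = 1.42e-09, or 0.0512 with an estimated correlation). They included the ribonucleotide reductase subunit RRM2B (log2 fold change 2.31), the translesion polymerase POLH (2.33) and the damage sensor XPC (1.31). Of 25 p53-activated genes of metabolism and transport, 23 rose and 2 did not pass (median 2.15, camera adjusted p = 2.15e-27). The mitochondrial reductase FDXR (3.18) and the pantothenate kinase PANK1 (2.69) were among them, and the lipid transfer gene PLTP rose from 381 to 2446 TPM (2.86). Of 44 other p53-activated genes, 38 rose and 6 did not pass (median 1.91, camera adjusted p = 4.46e-36). The plexin gene PLXNB3 rose from 1.98 to 64.6 TPM (5.15), EPS8L2 from 39.4 to 387 TPM (3.53) and HES2 from 0.82 to 25.95 TPM (5.39). The edgeR adjusted p-values of the genes taken from these 5 lists by the naming rule ran from 3.1e-07 to 8.59e-06. With p adjusted over the list alone, the counts of all 5 lists were the same, and apart from the repair list each kept its call with an estimated correlation (adjusted p = 0.0229 to 0.0354).

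Genes of the cell cycle fell together. Of 55 tested genes of G2/M and mitosis, 54 fell and 1 did not pass, with a median log2 fold change of -4.57 (camera adjusted p = 1.27e-59, or 0.162 with an estimated correlation). CDK1, the kinase that drives entry into mitosis, fell from 31.9 ± 4.95 to 1.16 ± 0.217 TPM (-4.56), and the transcription factor gene MYBL2 from 23.4 ± 8.05 to 0.15 ± 0.0361 TPM (-7.18), beside MKI67. The member that did not pass was the phosphatase gene CDC25B at -0.23 (edgeR adjusted p = 0.0488 with the replicate block). Of 45 genes of the G1/S transition and DNA replication, 37 fell, 3 rose and 5 did not pass, with a median of -1.72 (camera adjusted p = 1.52e-24, or 0.188 with an estimated correlation). CLSPN, a mediator of the replication checkpoint (-5.10), and E2F1, a transcription factor of S-phase entry (-3.52), fell beside MCM10. The 3 that rose were the sliding clamp PCNA (2.20), the DNA ligase LIG1 (1.42) and the thymidylate synthase TYMS (1.30).

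Of 21 genes of homologous recombination and Fanconi anaemia repair, 20 fell and 1 did not pass, with a median log2 fold change of -3.26 (camera adjusted p = 4.47e-28, or 0.0512 with an estimated correlation). FANCI fell from 33.7 ± 5.07 to 1.19 ± 0.0551 TPM (-4.42), its partner FANCD2 from 13.3 ± 2.14 to 0.527 ± 0.227 TPM (-5.64), and the recombination factor gene RAD51AP1 from 17.8 ± 3.82 to 0.21 ± 0.02 TPM (-6.48). The member that did not pass was PALB2 at 0.05. The edgeR adjusted p-values of the genes named by rule from these 3 lists ran from 1.39e-06 to 4.29e-06. In edgeR adjusted over the list alone, the counts of the mitosis, replication and recombination lists were the same. PCNA, LIG1, TYMS, CDC25B and PALB2 were singled out after their values were seen. Of 23 listed replication-dependent histone genes, 12 had too few counts to be tested, with at most 2 TPM in any library. The list therefore does not show how histone mRNAs as a whole changed. Of the 11 tested, 0 passed in edgeR, adjusted over all genes or adjusted over the list alone (median -0.07, camera adjusted p = 0.791). At an unadjusted p 2 were higher and 1 lower, DESeq2 called 1 higher, and limma on log2(TPM + 1) called 2 lower. With the replicate block 2 histone genes were called higher, as was 1 without DMSO replicate 1, and 1 was called lower without DMSO replicate 2.

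Outside those lists, 6 of 11 tested members of the BCL2 family rose, 1 fell and 4 did not pass. The list's median log2 fold change was 0.44 (camera adjusted p = 0.0044, or 0.188 with an estimated correlation). When adjusted over the list alone, 6 rose and 2 fell. The count of falls was 2 with the replicate block and without idasanutlin replicate 3, and 0 without DMSO replicate 1, DMSO replicate 3, idasanutlin replicate 1 or idasanutlin replicate 2. The BH3-only gene BIK, which promotes apoptosis, rose from 0.483 ± 0.176 to 21.6 ± 4.11 TPM (5.66), and the effector BAK1 from 13.4 ± 1.77 to 36.2 ± 1.82 TPM (1.62). BCL2L1, which encodes the survival protein BCL-XL, also rose, from 58.4 ± 3.14 to 140.5 ± 5.05 TPM (1.64). The 1 that fell, HRK, was singled out after its value was seen and, like BIK, encodes a BH3-only protein that promotes apoptosis. The edgeR adjusted p-values of BIK, BCL2L1 and BAK1 ran from 4.72e-06 to 4.31e-05.

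Genes of the integrated stress and unfolded protein responses were lower. Of 21 tested, 16 fell, 2 rose and 3 did not pass, with a median log2 fold change of -0.82 (camera adjusted p = 0.000616, or 0.511 with an estimated correlation). Adjusted over the list alone, 17 fell and 2 rose. The serine synthesis genes PHGDH and PSAT1 fell from 264 ± 25.1 to 106 ± 11.3 TPM (-1.13) and from 603 ± 76.1 to 249.6 ± 20.8 TPM (-1.09). The asparagine synthetase gene ASNS fell from 427 ± 37.3 to 193 ± 18.3 TPM (-0.98). The edgeR adjusted p-values of these 3 ran from 0.00022 to 0.000617. The 2 that rose, SDF2L1 (1.05) and PDIA4 (0.45), encode proteins of folding in the endoplasmic reticulum and were singled out after their values were seen.

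**Figure D3:**
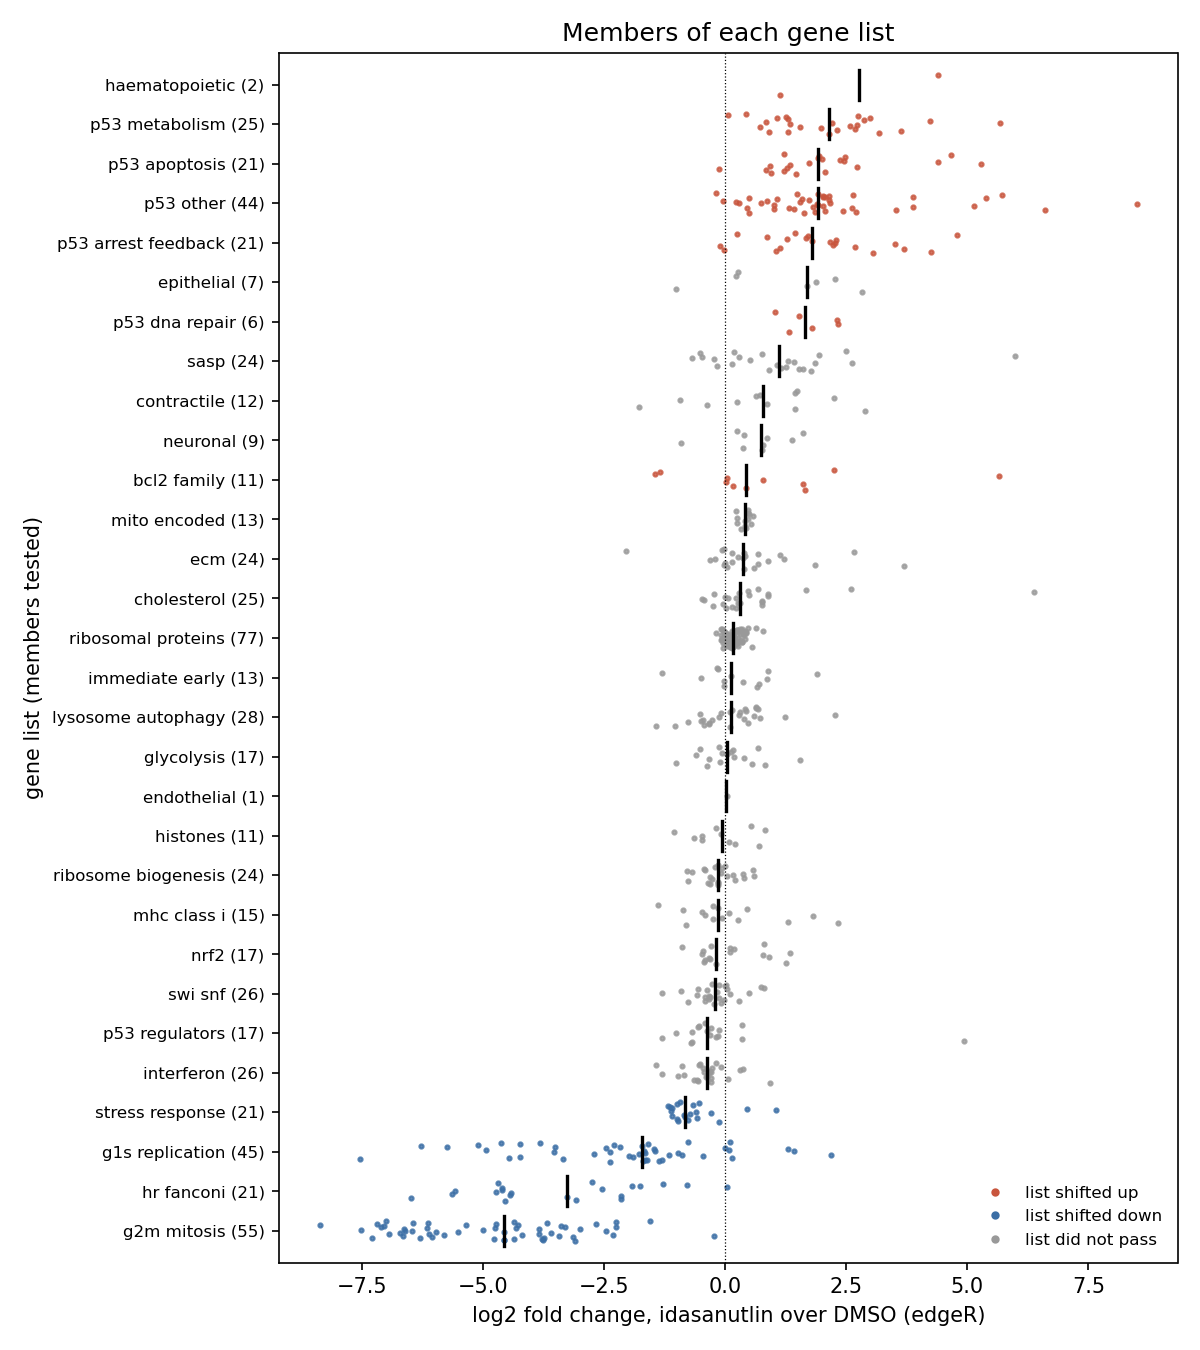
log2 fold change of idasanutlin over DMSO from edgeR (horizontal axis) for every tested member of each gene list (vertical axis, with the number tested in brackets), with a point per gene and a bar at the list's median. Red lists passed camera upward, blue lists passed downward and grey lists did not pass. Medians run from -4.57 for mitosis genes to 2.77 for the haematopoietic list, which had 2 tested members.

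Regulators of p53 other than MDM2 moved apart: of 17 tested, 3 rose, 6 fell and 8 did not pass (median -0.37, camera adjusted p = 0.187), with the same counts adjusted over the list alone. TP73, a gene of the p53 family, rose from 0.147 ± 0.0379 to 4.04 ± 0.951 TPM (4.94, edgeR adjusted p = 4.59e-06), and the others that rose were MDM4 and the ubiquitin ligase gene RFWD2. Of 26 tested SWI/SNF subunits, 4 rose, 6 fell and 16 did not pass (median -0.20, camera adjusted p = 0.253), again with the same counts adjusted over the list alone. With the replicate block, 10 regulators of p53 and 12 SWI/SNF subunits fell. BCL7A rose by 0.75 on the log2 scale (edgeR adjusted p = 0.000537) along with SS18L1, BRD9 and SMARCD1. The core subunit SMARCC1 fell by 0.77 (edgeR adjusted p = 0.000719). RFWD2, SS18L1, BRD9 and SMARCD1 were picked after their values were seen. On log2(TPM + 1), RFWD2 (limma adjusted p = 0.55), BRD9 (0.0503) and SMARCD1 (0.177) lost their call.

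Of 24 genes of ribosome biogenesis with MYC, 8 fell, 4 rose and 12 did not pass (median -0.14, camera adjusted p = 0.253). With p adjusted over the list alone, 9 fell and 4 rose. The nucleolar GTPase GNL3 fell by 0.79 (edgeR adjusted p = 0.00145) and the assembly factor RRS1 rose by 0.58 (0.00161 by edgeR), while the others that rose, BOP1, RRP9 and POLR1A, were picked after their values were seen. The count of falls was 4 without DMSO replicate 1, idasanutlin replicate 2 or idasanutlin replicate 3, and 5 without DMSO replicate 3, and the count of rises was 2 without DMSO replicate 3 or idasanutlin replicate 3. Of 77 genes of cytosolic ribosomal proteins, 16 rose, 0 fell and 61 did not pass (median 0.16, camera adjusted p = 0.187). In edgeR adjusted over the list alone, 5 rose. RPS19 rose by 0.79 (edgeR adjusted p = 0.000566). On log2(TPM + 1) the median of the ribosomal protein genes was 0, with 4 higher and 1 lower, and 5 rose without DMSO replicate 3 or idasanutlin replicate 1 and 10 without idasanutlin replicate 3.

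Of 25 genes of cholesterol synthesis and uptake, 5 rose and 20 did not pass (median 0.30, camera adjusted p = 0.187), or 4 adjusted over the list alone. TM7SF2, a sterol reductase, rose from 11.2 ± 1.39 to 63.9 ± 7.38 TPM (2.61, edgeR adjusted p = 4.13e-06). PMVK, HSD17B7 and STARD4 rose as well and were picked after their values were seen. With the replicate block, 11 genes of this list rose and 2 fell, and 1 fell without DMSO replicate 2. The median was 0.01 without DMSO replicate 2, -0.02 without idasanutlin replicate 1, 0.59 without DMSO replicate 3, 0.18 without idasanutlin replicate 3 and 0.68 without idasanutlin replicate 2. Without idasanutlin replicate 2, 11 genes rose (camera adjusted p = 0.00729), and without both number 2 libraries 12 rose and 2 fell (0.0429 by camera).

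Of 17 glycolysis genes, 5 rose, 3 fell and 9 did not pass (median 0.04, and -0.10 on log2(TPM + 1); camera adjusted p = 0.655), with the same counts adjusted over the list alone. The liver-type phosphofructokinase PFKL rose from 59.6 ± 11.1 to 157 ± 3.2 TPM (1.55, edgeR adjusted p = 3.75e-05) and the hexokinase HK1 by 0.55 (0.00233 by edgeR), with SLC2A3, PFKP and PKM, while HK2, PFKM and ENO1 fell. The number of glycolysis genes that fell was 5 with the replicate block, 0 without DMSO replicate 1 or idasanutlin replicate 2, and 1 without DMSO replicate 3, idasanutlin replicate 1 or idasanutlin replicate 3. Their median ranged from -0.05 without idasanutlin replicate 1 to 0.14 without DMSO replicate 1. Of 17 antioxidant targets of NRF2, 4 rose, 4 fell and 9 did not pass, or 5 and 5 adjusted over the list alone (camera adjusted p = 0.769). Their median was -0.19 while their mean was 0.10 and camera's direction was up. The transketolase gene TKT (1.34, edgeR adjusted p = 6.3e-05) of the pentose phosphate pathway rose with PGD and PRDX1, while GCLC, TALDO1, PIR and GSR fell. The number of NRF2 targets that fell was 1 without DMSO replicate 1, DMSO replicate 3 or idasanutlin replicate 2, 2 without idasanutlin replicate 1 or 3, and 8 without DMSO replicate 2. Members named here without a value were picked after their values were seen.

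Of 28 lysosome and autophagy genes, 8 rose, 7 fell and 13 did not pass (median 0.13, camera adjusted p = 0.693), with the same counts adjusted over the list alone. The lysosomal protease CTSD rose from 206 ± 53.9 to 902 ± 81.3 TPM (2.28, edgeR adjusted p = 4.98e-05) and the protective protein CTSA from 147 ± 30.6 to 438 ± 34.8 TPM (1.23, 0.000369 by edgeR). CTSA overlaps PLTP, which also rose, on the opposite strand, so part of its rise may be reads of PLTP. The number of lysosome and autophagy genes that fell was 2 without DMSO replicate 1 or 3, 3 without idasanutlin replicate 2 or 3 and 4 without idasanutlin replicate 1, and 5 rose without idasanutlin replicate 1 or 3. With the replicate block, 12 rose and 10 fell. The median of these genes was -0.07 without DMSO replicate 2, 0.25 without DMSO replicate 1 and 0.24 without DMSO replicate 3 or idasanutlin replicate 2.

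Of 26 tested interferon-stimulated genes, 2 rose, 3 fell and 21 did not pass (median -0.38, camera adjusted p = 0.158), and adjusted over the list alone 0 rose and 1 fell. With the replicate block, 3 rose and 14 fell. At an unadjusted p, 3 were higher and 6 lower. OASL fell from 10.5 ± 2.77 to 3.79 ± 0.857 TPM (-1.31, edgeR adjusted p = 0.00208), with IFIT2 and HERC5. ISG15 rose from 284.5 ± 57.5 to 483 ± 206 TPM (0.92, edgeR adjusted p = 0.0228), with IFI44. ISG15 lost its call without DMSO replicate 1 (0.0771), DMSO replicate 3 (0.0627) or idasanutlin replicate 2 (0.0533) and on log2(TPM + 1) (0.0723), within a range of adjusted p from 0.000176 to 0.0771. Without idasanutlin replicate 2, 17 genes of the list fell and 0 rose (camera adjusted p = 9.34e-05). The count of falls was 1 without DMSO replicate 1, DMSO replicate 3, idasanutlin replicate 1 or idasanutlin replicate 3. The count of rises was 0 without DMSO replicate 1 or 3 and 1 without idasanutlin replicate 3. Without both number 2 libraries, 18 fell and 1 rose (camera adjusted p = 0.000296). IFIT2, HERC5 and IFI44 were picked after their values were seen.

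Of 15 genes of MHC class I antigen presentation, 4 rose, 3 fell and 8 did not pass, with the same counts adjusted over the list alone (camera adjusted p = 0.372). Their median was -0.15 while their mean was 0.11 and camera's direction was up. The count of falls in this list was 1 without DMSO replicate 2, idasanutlin replicate 1 or idasanutlin replicate 3. With single libraries left out their median ranged from -0.40 (idasanutlin replicate 2) to 0.09 (DMSO replicate 2). The peptide transporter TAP1 rose from 41.4 ± 2.07 to 127 ± 12.1 TPM (1.82, edgeR adjusted p = 6.03e-06) and HLA-B from 21.6 ± 6.47 to 97.0 ± 10.98 TPM (2.33, 3.58e-05 by edgeR), with HLA-C and PSMB10. PSMB9 and NLRC5 fell, and these genes, HLA-C and PSMB10 were picked after their values were seen.

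Of 24 secreted factors of senescent cells, 10 rose, 3 fell and 11 did not pass (median 1.11, camera adjusted p = 0.123, or 0.0211 with the replicate block). When adjusted over the list alone, 12 rose and 3 fell, and with the replicate block 15 rose and 4 fell. The growth factor AREG rose from 0.257 ± 0.286 to 12.01 ± 3.66 TPM (5.98, edgeR adjusted p = 0.000114). VEGFA, HGF and PLAU fell and were picked after their values were seen. Without DMSO replicate 3, 6 of these factors rose, and without idasanutlin replicate 3 the camera adjusted p was 0.0486.

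Of 24 extracellular matrix genes, 8 rose, 1 fell (FBLN1) and 15 did not pass (median 0.38, camera adjusted p = 0.0879, or 0.0497 without DMSO replicate 2), with the same counts adjusted over the list alone, and 2 fell with the replicate block. The laminin LAMC1 rose by 1.21 (edgeR adjusted p = 1.94e-05) and the collagen COL5A1 by 1.86 (2.13e-05 by edgeR). Of 12 smooth muscle and contractile genes, 6 rose, 2 fell (CNN1 and MYH11) and 4 did not pass, with the same counts adjusted over the list alone. Their median was 0.79 (camera adjusted p = 0.0559), and camera gave 0.0136 with the replicate block, 0.0294 without idasanutlin replicate 1 and 0.0203 without idasanutlin replicate 3. Without any 1 library other than DMSO replicate 2, 1 of these genes fell. Smooth muscle actin ACTA2 rose from 31.5 ± 3.87 to 198 ± 13.1 TPM (2.90, edgeR adjusted p = 1.39e-06) and the actin-binding CALD1 from 0.683 to 2.51 TPM (2.26, 0.00023 by edgeR). Of 9 neuronal genes, 4 rose, 1 fell (SYP) and 4 did not pass (median 0.75, camera adjusted p = 0.17). Adjusted over the list alone, 6 rose and 1 fell. The neurofilament NEFL rose by 1.38 (edgeR adjusted p = 9.83e-05) and the tubulin TUBB3 by 0.75 (0.00249 by edgeR), with ENO2 and CHGA. FBLN1, CNN1, MYH11, SYP, ENO2 and CHGA were picked after their values were seen.

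Lists of other cell types and of RNA quality were read as checks. Of the haematopoietic markers, 2 had enough counts to be tested and both rose (median 2.77, camera adjusted p = 0.0289, or 0.354 with an estimated correlation and 0.0637 without DMSO replicate 2), with the same counts adjusted over the list alone. They were the globin HBA1, from 1.597 ± 0.614 to 30.3 ± 11.3 TPM (4.39, edgeR adjusted p = 7.59e-05), and the lysosomal protein CD68, from 27.6 ± 3.95 to 55.4 ± 6.39 TPM (1.15, 0.000274 by edgeR). The 10 untested markers, which include PTPRC of all white blood cells and the globin HBB, had at most 0.45 TPM in any library. Of 7 tested epithelial markers, 3 rose and 4 did not pass (median 1.69, camera adjusted p = 0.224), or 4 rose adjusted over the list alone. On log2(TPM + 1) their median was 0.32, with 3 higher and 1 lower. The 5 untested markers, EPCAM, KRT5, KRT14, KRT18 and GRHL2, had at most 0.19 TPM in any library. CLDN4 rose from 0.89 ± 0.156 to 4.06 ± 0.469 TPM (2.27, edgeR adjusted p = 9.38e-05), CDH1 from 0.0867 ± 0.0577 to 0.36 ± 0.09 TPM (2.82, 0.00118 by edgeR), and KRT8, picked after its value was seen, also rose. The rise of CDH1 rests on few reads, with 7 counts over the DMSO group and 46 over the idasanutlin group. It was tested only through its counts under idasanutlin. The 1 tested endothelial marker, EGFL7, was at 0.03 and did not pass (camera adjusted p = 0.974, direction down), and 0 passed adjusted over the list alone or at an unadjusted p.

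All genes with a symbol that starts with MT-, a set not limited to mRNAs, took 3.05% ± 0.356 of the counts in DMSO and 3.81% ± 0.271 under idasanutlin. Of the 13 listed mitochondrially encoded mRNAs, 8 rose and 5 did not pass (median 0.42, camera adjusted p = 0.106), or 10 rose adjusted over the list alone. MT-ND6 rose by 0.47 (edgeR adjusted p = 0.00454) and MT-ND4 by 0.53 (0.00961 by edgeR). MT-ND4 lost its call without idasanutlin replicate 3 (0.0502) and on log2(TPM + 1) (0.0576), within a range of adjusted p from 0.000473 to 0.0576. Without single libraries other than idasanutlin replicate 2, 3 to 5 of the mitochondrial genes rose, on log2(TPM + 1) 1 did, and the camera adjusted p was 0.0467 without DMSO replicate 3 and 0.0417 with the replicate block. Of 13 immediate early genes, which respond to handling, 4 rose, 1 fell (ATF3) and 8 did not pass (median 0.13, camera adjusted p = 0.308), or 5 and 1 adjusted over the list alone. IER3 rose by 1.90 (edgeR adjusted p = 5.78e-05) and FOS by 0.65 (0.0013 by edgeR), with JUN and DUSP1. ATF3, JUN and DUSP1 were picked after their values were seen.

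In all, 11 of the 30 lists passed camera, 4 of them with an estimated correlation. Every other split of the libraries into 3 and 3 passed 11 to 17 lists as well. The number of passes at the preset correlation therefore does not set the treatment apart. Relative to the shift of all genes on log2(TPM + 1), the medians were 1.58 to 1.81 for the p53 target lists, -3.29 for mitosis, -1.51 for replication, -1.82 for recombination, 0.53 for the BCL2 family, -0.84 for the stress responses and 2.42 for the haematopoietic markers. On log2(TPM + 1) itself, 1 of the p53 regulators was called higher and 10 lower, 2 and 12 of the SWI/SNF subunits, 2 and 14 of the ribosome biogenesis genes, 0 and 8 of the interferon-stimulated genes, 4 and 2 of the matrix genes, 5 and 6 of the lysosome and autophagy genes and 7 and 1 of the contractile genes. Of the list members picked after their values were seen, BOP1, CNN1, ENO1, GCLC, GSR, HERC5, HGF, HK2, HRK, HSD17B7, IFI44, IFIT2, PFKM, PFKP, POLR1A, PSMB10, PSMB9, RFWD2, SLC2A3, SMARCD1 and TALDO1 lost their call with 1 or more single libraries left out (edgeR adjusted p = 0.0513 to 0.176). Beside RFWD2, BRD9 and SMARCD1, those that lost it on log2(TPM + 1) were BOP1, CNN1, HERC5, HRK, HSD17B7, IFI44, POLR1A and PSMB10 (limma adjusted p = 0.05 to 0.621). PFKP lost it on log2(TPM + 0.1) (0.0513) and GSR by DESeq2 (0.0725). Among the other lists that did not pass camera, leaving out single libraries moved the median to between -0.87 and -0.21 for interferon-stimulated genes, 0.60 and 1.69 for senescence factors, 0.08 and 0.48 for immediate early genes, -0.31 and -0.08 for NRF2 targets, 0.19 and 0.39 for matrix genes and 0.68 and 1.2 for contractile genes. The median then lay between -0.22 and 0 for histone genes and between 0.10 and 0.20 for ribosomal protein genes.

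The library kit does not mark strand, so reads of overlapping antisense genes cannot be told apart, and neither can those of near-identical copies. By the GENCODE 29 annotation, BCL2L1 shares 43% of its exonic length with an antisense gene, RFPL1 78.2%, TYMS 39.1%, IER3 26.5%, XPC 23.8%, PRDX1 24.9%, PLAU 31.1% and HHATL-AS1 54.8%. On the same strand, CD68 shares 81.7% with another gene, ASNS 44.6%, CTSD 41.7%, TUBB3 35.8%, PSMB10 34.8%, TNFRSF10C 26%, IGF2 20.9% and PLXNB3 20.4%. IGF2 also shares 73.7% with a second entry of its own name. ACTA2 shares 12.8% with the p53 target FAS and SMARCB1 17.7% with DERL3, each on the opposite strand. CTSA shares 200 exonic bases with PLTP on the opposite strand, 3.42% of the exonic length of CTSA. Counts summed over a group went from 38673 to 247480 for PLTP and from 14843 to 30234 for CTSA. Reads of PLTP could therefore make up part of the rise of CTSA, which was not tested. DUX4L11, LGALS7B, HBA1 and AREG have near-identical copies, and the posterior SD of their counts was 13.3%, 5.18%, 3.3% and 15.2% of the count, so their levels are uncertain.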

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

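Leaving out both number 2 libraries was chosen only after the data were seen, and so were the genes named outside the rule. The number of changed genes ranged from 5496 (without DMSO replicate 3) to 8837 (replicate block), against 6960. Of the 6960 genes called in the main fit, 0 passed with the opposite sign under any alternative. Genes not called in the main fit were not checked for this. Of 1247 recomputed values of the 78 genes named by the rule, 1234 kept their direction and their side of the threshold, 9 no longer passed, 4 newly passed and 0 reversed, and 74 genes kept their call throughout (the others were ISG15, MDM4, MT-ND4 and SMARCB1). Of 1506 values of the 95 genes picked later, 1359 stayed, 132 no longer passed, 3 newly passed and 12 reversed, the last all in genes that had not passed. The replicate block changed the call of SMARCB1 (0.04), CDC25B (0.0488) and RFPL1 (0.0452) and of no other named gene. Among the reversed values, EGFL7 was at -0.01 with upper-quartile factors, -0.10 on log2(TPM + 1) and -0.11 on log2(TPM + 0.1). PALB2 was at -0.08 and -0.09 on those TPM scales and -0.06 without both number 2 libraries, where TNFRSF10C was at 0.01. Those scalings shift all genes, with a median of -0.068 with upper-quartile factors and -0.147 on log2(TPM + 1), relative to which EGFL7 was at 0.05 and PALB2 at 0.07 on log2(TPM + 1). With single libraries left out, EGFL7 ranged from -0.03 to 0.10, PALB2 from -0.05 to 0.15 and TNFRSF10C from -0.45 to 0.35. On log2(TPM + 1), 1060 genes were higher past a doubling. The cause was not tested.

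With an estimated correlation 4 lists passed, and camera's adjusted p became 0.0512 for p53 repair targets and for recombination, 0.188 for replication and for the BCL2 family, 0.162 for mitosis, 0.511 for stress responses and 0.354 for haematopoietic markers. By fry 20 lists passed, among them p53 regulators (0.0158), SWI/SNF (0.0253), senescence factors (0.0275), matrix (0.00916), contractile (0.00827), neuronal (0.000699), immediate early (0.000463), mitochondrial (0.0257) and epithelial genes (0.00787). The replicate block changed camera's call of senescence factors (0.0211), contractile (0.0136) and mitochondrial genes (0.0417) and of no other list. Apart from the counts of list members printed with the block, it moved no count of them by over 1.5 times. Fry with the block passed senescence factors (0.0182), matrix (0.00753), contractile (0.0156), neuronal (0.00173) and immediate early genes (0.00962). On log2(TPM + 1), senescence factors (0.015), contractile (0.026), neuronal (0.0282), mitochondrial (0.00839) and epithelial genes (0.0447) passed camera. Without both number 2 libraries, cholesterol (0.0429), interferon (0.000296), senescence factors (0.0429) and matrix genes (0.0429) did. With single libraries left out, camera's adjusted p ranged from 0.0497 to 0.135 for matrix, 0.00515 to 0.0637 for haematopoietic, 0.0467 to 0.2 for mitochondrial, 0.0203 to 0.0858 for contractile, 0.00729 to 0.599 for cholesterol and 9.34e-05 to 0.313 for interferon genes, and from 0.0486 to 0.192 for senescence factors. The cause was not tested. Depth limits the genes at 0 to 3 counts in a group, for which only a bound or a wide interval can be given, and the test recovered 16% of simulated changes of 1.5-fold.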

Other observations

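The tests on DUX4, the lists of DUX4 targets and epidermal genes and all genes named in these first paragraphs were chosen after the gene table was seen. Genes that the embryonic transcription factor DUX4 is known to activate in cleavage-stage embryos and in muscle were mostly higher under idasanutlin. Of 24 listed, 2 had too few counts to be tested (at most 1.11 TPM). Of 22 tested, 20 had under 1 TPM in DMSO, the others being MBD3L2 and PITX1 (39.07 TPM). Of the 22, 20 rose, 1 fell (PITX1) and 1 did not pass (RFPL1, edgeR adjusted p = 0.101, or 0.0452 with the replicate block and 0.0395 without DMSO replicate 1), with a median log2 fold change of 6.59 when genes with no DMSO counts are set at their bound (camera p = 6.72e-28, or 0.037 with an estimated correlation and 4.77e-25 with the replicate block). ZSCAN4 rose from 0.377 ± 0.254 to 31.5 ± 6.52 TPM (edgeR adjusted p = 5.12e-06), TRIM43 from 0.133 ± 0.0322 to 20.9 ± 2.45 TPM (6.18e-07 by edgeR) and MBD3L2 from 1.02 ± 0.792 to 99.3 ± 22.5 TPM (6.55e-06 by edgeR). LEUTX, TRIM51 and DUXA had 0 counts in DMSO and were at least 34.8-fold, 46.2-fold and 21.4-fold higher. Of the 22, 0 belong to a list fixed in advance. In DMSO 6 of them had 3 or fewer counts, and others also had few, such as TRIM43 (14) and TRIM48 (12). Such genes could pass the filter only through their counts under idasanutlin, so their rise was nearly fixed in advance. Neither the share that rose nor the camera p therefore describes the whole list.

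Some genes of the epidermis rose as well. Of 34 listed, 15 had too few counts to be tested, among them KRT5 and KRT14 of basal cells, with at most 0.8 TPM in any library. Of the 19 tested, 15 rose, 1 fell (KRT10) and 3 did not pass (KRT16, FLG and TP63). In DMSO 9 of the 19 had 3 or fewer counts, and others also had few, such as LGALS7 (5) and KRT15 (13). Such genes were tested only through their counts under idasanutlin, so the share that rose does not describe the whole list. The 14-3-3 sigma gene SFN rose from 61.8 ± 6.38 to 839 ± 94.9 TPM (edgeR adjusted p = 8.43e-07) and the keratin gene KRT17 from 2.32 ± 1.2 to 127 ± 38.3 TPM (1.55e-05 by edgeR). Of the 19, 4 also stand in lists fixed in advance, 3 of them in those of p53 targets. CLCA2, which p53 can activate, is among the 19 but in none of those lists, so 3 is a minimum. KRT10, KRT15 and TGM1 lost their call with 1 or more single libraries left out (edgeR adjusted p = 0.0546 to 0.126), TGM1 also with upper-quartile factors (0.0514). Among abundant transcripts, the imprinted non-coding RNA H19 rose from 35.3 ± 19.1 to 2378 ± 526 TPM (log2 fold change 6.24, SE 0.398, edgeR adjusted p = 8.41e-06). Its imprinted neighbour IGF2 rose from 0.77 ± 0.0608 to 4.01 ± 0.697 TPM (0.000158 by edgeR). The GABA receptor subunit gene GABRD rose 978-fold, from 0.37 ± 0.171 to 316 ± 39.6 TPM (3.1e-07 by edgeR), and the small GTPase gene RRAD 388-fold, from 0.483 ± 0.112 to 155 ± 7.69 TPM (1.24e-07 by edgeR).

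Transcripts assigned to DUX4 and DUX4-like copies rose beside the DUX4 targets, although the rise of DUX4L11 had been seen before that test. Whether the 2 rises are linked stays open. The summed CPM of 19 DUX4 and DUX4-like copies were at least 13.5 in each idasanutlin library and at most 0.0681 in DMSO, with 64.5% to 87.4% of them assigned to DUX4L11. The row of DUX4 itself had 0 counts in every library but idasanutlin replicate 3, where it had 1.58, so which copy was transcribed also stays open. For the 11 targets whose posterior SD is at most 1% of the count, reads shared between near-identical copies are argued against as the source. Their log2 fold changes had a lower quartile of 5.43, although these rises had also been seen before the test was set. The other targets are not covered. Of 43481 other genes under 1 TPM in DMSO, 2.17% reached 1 TPM (exact 95% interval 2.04 to 2.31). Most of these genes therefore did not reach that level. They include genes without counts in any library, which lowers the share, and the targets were listed after their rise was seen. The share therefore does not decide whether silent genes were released in general, which stays open. The release of a smaller set that includes these targets stays open too. Whether DUX4 drives these genes here, and how p53 activity relates to it, was not tested.

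Same-numbered libraries of the groups deviated together. This could have come from the number 2 libraries alone, which stand apart on the second principal component, but the difference between libraries 1 and 3 still correlated at 0.43 between the groups. A shared day or batch of cells, library making or sequencing for each number stays open, since the labels give none. Luck stays open too, since so few libraries can be matched in few ways.

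Of the 10 splits of the 6 libraries into 3 and 3, 1, the real one, gave as many changed genes (6960, against 0 for the highest other by edgeR), and 10 splits are too few for a share under 0.05. The other splits gave 34 to 601 genes at an unadjusted p and 0 by limma-voom. For lists, all 10 splits passed at least the 11 of the real one, and the highest other passed 17. The number of lists passed at the preset correlation therefore does not set the real grouping apart. Every other split leaves libraries of both treatments in both groups in unequal numbers, so part of the treatment difference remains in it. The rest of that difference goes into the spread within the groups, which by itself keeps the calls low. The 0 genes of the other splits therefore do not decide whether the grouping arose by luck. Of those 9, 3 part all 3 same-numbered pairs, as the real split does (0 genes, 11 to 16 lists), and 6 part 1 pair (0 genes, 13 to 17 lists).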
